A study of Homo sapiens with 16 samples.

How the data were processed

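The series holds 16 arrays of a 2-colour Agilent gene expression design, each with RNA of MDA-MB-231 cells given a compound (Cy3) and RNA of untreated cells (Cy5), in 4 groups of 4 arrays: compound 3 or compound 6 for 24 h or 48 h. Every array has 62976 spots, of which 4259 are controls, and 42405 different probes.

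Per the file headers, the spots were read with Feature Extraction 10.7.3.1 and annotated on hg19. The deposited intensity values are the mean spot signal and the median local background of each channel, which carry no processing beyond the scan, and processed signals that the scanner software had background-subtracted, detrended and dye-normalized by a linear and a lowess step. The deposited log10 ratios are those of red over green, untreated over treated, per the file headers. The other deposited values used are flags of 0 or 1 per spot and channel for signal well above background, for outliers and for saturation, per the file headers. The authors' value table holds log2 ratios of treated over untreated. Its column medians run from -0.17 to 0.04, and how it was made is not stated; which of scaling, centring or choice of spots sets these medians is unknown. Of the 16 scanner files 15 matched a column of these values at r = 1; 4 matched the column with the same label and 11 that of another replicate of the group, so the authors' replicate numbers entered only the authors' table and the later alternatives and tests that name them.

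Mean signals were background-corrected by normexp with an offset of 50 and normalized within arrays by loess on the non-control spots, with limma 3.58.1 in R 4.3.3 and version 1.17.8 of data.table. Spots marked as outliers were removed, the remaining spots of a probe were averaged, and 25 probe values were missing. Log ratios were turned to treated over untreated. A probe was kept if it was well above background on all 4 arrays of at least 1 group in either channel, which left 21547 probes. The brightest kept probe stood for its gene, for 17356 genes, of which 3518 had several kept probes. Current symbols came from the RefSeq accessions of the probes: 25422 of 27310 were matched, and the symbol of 2216 kept probes differed from that in the files. Median signals ran from 97.8 to 117 in the treated channels and from 129 to 142 in the untreated ones, 405 to 845 spots per array were marked as outliers, and before normalization the median log2 ratio of an array was between -0.52 and -0.24.

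A single limma model with a mean for each group was fitted to the log ratios of all 16 arrays. It gave each group against untreated cells, compound 6 minus compound 3 at each time, 48 h minus 24 h for each compound, and the interaction of compound and time. Untreated cells at 48 h and 24 h were compared in the untreated channel after quantile normalization of the average intensities, 8 channels per time. Gene p-values were moderated by empirical Bayes and adjusted by the Benjamini-Hochberg method within a comparison, with a threshold of 0.05. The 39 gene lists were written from general knowledge before the data were examined, as were the comparisons, the settings above and all alternatives except those named below as later. Lists were tested with camera at a preset correlation of 0.01 between genes and adjusted over the lists of a comparison.

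Genes were named by a rule: in each comparison the 8 largest rises and the 8 largest falls among called genes with a proper symbol, the same sign on all 4 arrays or groups that do not overlap, and signal well above background, then up to 4 called members of each list and the members called the opposite way. EZH2, EHMT2, EHMT1, SUZ12 and EED were always given. Some members called against their list did not have the same sign on every array.

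The alternatives were no background subtraction, the scanner's processed signals centred on the array median, median centring in place of loess, quantile normalization of the untreated channel alone, no filter and a strict filter (both channels on all arrays), slide as a fixed or a random block, the replicate number as a block, only the groups compared, the mean over probes, the authors' table, the treated channel alone for differences between groups, each array left out in turn, camera with an estimated correlation, and fry. Added after the data were seen were the lists without compound 6 24 h replicate 4, the authors' table with a replicate block, 5 arrays left out together, correlations by the table's own replicate numbers, untreated channels averaged over equal numbers of that table, and 48 h arrays paired by them. Camera with estimated correlation was also run without compound 6 24 h replicate 4. Real groupings were set against other splits of the arrays. Shared untreated RNA was simulated 20 times.

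The code was tested on simulated data with 100 changed genes of each size: for compound 3 at 48 h all genes of log2 0.5 and 1 were found with 9 false calls, and for the difference between compounds at 48 h 94% and 100% with 6 false calls. No array was left out of the fits described here.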

Results

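Transcripts were measured in MDA-MB-231, an established human breast cancer cell line, after treatment with 1 of 2 compounds that the labels name only by number. Compound 3 is labelled an inhibitor of EZH2, the catalytic subunit of the Polycomb complex PRC2 that methylates H3K27. Compound 6 is labelled an inhibitor of G9a, the H3K9 methyltransferase encoded by EHMT2, whereas the series title names EZH2 inhibitors only, so that its intended target stays open. Each compound was given for 24 h or 48 h, with 4 arrays for each of the 4 groups and 16 arrays in all. Every array held treated RNA in Cy3 and untreated RNA in Cy5, so that each time also had 8 untreated channels. Doses were not given, and the protocol text states 48 h and 72 h where the titles state 24 h and 48 h; the titles are followed here. Between 50.1% and 53.2% of the probes of an array were well above background in the treated channel, and between 48.0% and 51.6% in the untreated channel. The number of arrays limits the precision: the 95% interval of a difference between 2 groups reached a median of 0.17 to either side on the log2 scale. The labels give each replicate a separate untreated sample but do not state that the treated replicates were separate cultures. If they were not, the p-values measure only the spread between these samples.

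Values are log2 ratios of treated over untreated with the standard error from limma, n = 4 arrays per group, for 17356 tested genes, and probe positions are those of hg19. A gene is said to have risen or fallen where its adjusted p passed the threshold of 0.05. Gene lists carry adjusted p by camera, at a preset correlation between genes and then, marked estimated, at an estimated one. No dyes were swapped, so a probe's dye preference cannot be told apart from treatment against untreated cells, nor can DMSO of the compound stocks. The dye preference cancels in a difference between groups. The arrays lay on 3 slides, with all of compound 6 at 24 h on slide 2 and the other groups spread over 2 or 3 slides. The array labelled compound 6 24 h replicate 4 resembled compound 3 more than its own group. Across genes, which are not independent replicates, its log ratios correlated at r = 0.857 with the mean of compound 3 at 24 h and at r = 0.596 with the other 3 arrays of its group. It was also the only scanner file that matched no column of the authors' values, at r = 0.683 at most. Counts, the largest changes and several lists of compound 6 at 24 h are therefore also given without this array, a comparison added after the data were seen, while its other values include it.

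The comparison of compound 3 at 24 h with untreated cells asked which transcripts differed after the labelled EZH2 inhibitor. GDF15 rose most, by 2.65 ± 0.21 (adjusted p = 1.58e-07; chromosome 19, 18499890 to 18499949). Of 32 measured NF-kB and inflammatory cytokine genes 29 rose, with CSF3 at 2.08 ± 0.26, CXCL2 at 2.02 ± 0.24, IL6 at 1.95 ± 0.24 and CXCL1 at 1.87 ± 0.20 (median 0.74; camera 4.12e-12, 0.191 estimated). Of 26 genes of cholesterol biosynthesis and uptake 24 rose, with a median of 0.78 (camera 2.96e-11, 0.235 estimated). INSIG1 rose by 2.21 ± 0.29 and IDI1 by 1.19 ± 0.17. The efflux transporter gene ABCA1 fell most, to -1.52 ± 0.24 (chromosome 9, 107543704 to 107543763), and MYLIP stood at -1.08 ± 0.14. HKDC1 rose by 2.33 ± 0.22 and SOD2 by 1.81 ± 0.16. Each of these genes moved the same way on all 4 arrays.

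Genes of hypoxia response and glycolysis rose in 29 of 37 cases after 24 h of compound 3, with NDRG1 at 1.66 ± 0.13 and BNIP3 at 1.37 ± 0.14, while PKM2 fell to -0.15 ± 0.04 (median 0.46; camera 5.96e-12, 0.208 estimated). Lysosomal genes rose in 36 of 46 cases, with acid ceramidase ASAH1 at 1.04 ± 0.10 (median 0.31; 3.63e-11, 0.235 estimated). Of 39 autophagy genes 22 rose, with the cargo receptor SQSTM1 at 0.97 ± 0.11, and ULK2 fell to -0.20 ± 0.07 (median 0.19; 2.26e-05, 0.191 estimated). The unfolded protein response of the endoplasmic reticulum had 17 of 25 genes risen, led by HERPUD1 at 0.80 ± 0.06 (median 0.20; 9.67e-06, 0.178 estimated). Of 22 apoptosis regulators 15 rose and 2 fell, with the BH3-only genes BBC3 at 0.96 ± 0.09 and BMF at 0.61 ± 0.06 against BOK at -0.15 ± 0.04 and BIRC2 at -0.11 ± 0.04 (median 0.20; 0.00173, 0.191 estimated). Of 31 immediate early genes 16 rose, with IER3 at 1.06 ± 0.15, and FOSL1, DUSP2 and KLF10 fell to -0.27 ± 0.05, -0.24 ± 0.07 and -0.50 ± 0.10 (median 0.23; 0.000823, 0.553 estimated). NRF2 and oxidative stress genes rose in 16 of 26 cases, with HMOX1, the inducible heme oxygenase, at 1.32 ± 0.19 (median 0.21; 0.00328, 0.556 estimated). Among them PRDX1 fell to -0.19 ± 0.06, whose other probe had the opposite sign. Of 13 metallothionein and zinc transport genes 9 rose, with MT1F at 0.65 ± 0.11, and MT3 fell to -0.16 ± 0.04. The metallothionein median of 0.26 turned to -0.10 with median centring, -0.02 relative to all genes (0.00147, 0.340 estimated). Oxidative phosphorylation had 19 of 41 genes risen, with the coactivator PPARGC1A at 1.55 ± 0.09, and ATP5D and SDHA fallen to -0.30 ± 0.05 and -0.25 ± 0.04. The list's median of 0.08 turned to -0.23 with median centring, -0.14 relative to all genes (0.0130, 0.340 estimated).

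Cell division genes fell together after 24 h of compound 3. All 40 G2/M and mitosis genes fell, with CDC20, an activator of the anaphase-promoting complex, at -0.86 ± 0.08 and the mitotic kinesin KIF20A at -0.81 ± 0.12 (median -0.46; camera 3.27e-21, 0.191 estimated). Of 43 G1/S and DNA replication genes 41 fell, with E2F8 at -1.04 ± 0.07 and the thymidylate synthase gene TYMS at -0.75 ± 0.08 (median -0.37; 3.89e-19, 0.191 estimated). Of 30 replication-dependent histone genes 25 fell, with HIST1H2AB at -1.36 ± 0.12, HIST1H4C at -1.29 ± 0.11 and HIST1H3B at -1.08 ± 0.10 (median -0.46; 3.42e-14, 0.178 estimated). HIST1H4J stood at -1.05 ± 0.10 and CDCA7 at -1.03 ± 0.11, which completed the 8 largest falls. Cytosolic ribosomal protein genes fell in 43 of 50 cases (median -0.26; 2.63e-19, 0.178 estimated). Ribosome biogenesis genes fell in 23 of 40 cases, with the fibrillarin gene FBL at -0.35 ± 0.04 (median -0.14; 6.19e-06, 0.337 estimated). Antigen presentation genes fell in 11 of 22 cases, with CIITA, the class II transactivator, at -0.67 ± 0.06 (median -0.18; 0.00137, 0.358 estimated). Of 15 H3K9 methyltransferases and partners 9 fell, with UHRF1 at -0.85 ± 0.06 and DNMT1 at -0.56 ± 0.05 (median -0.16; 0.0108, 0.191 estimated). SETDB2, DNMT3A, DNMT3B and ZNF644 of that list rose by 0.49 ± 0.07, 0.25 ± 0.05, 0.24 ± 0.09 and 0.23 ± 0.06, another DNMT3A probe with the opposite sign.

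The transcript of the labelled target EZH2 itself fell to -0.72 ± 0.07 after 24 h of compound 3 (adjusted p = 6.46e-07; chromosome 7, 148504505 to 148504564). Its partner EED stood at -0.31 ± 0.04. The transcripts of EHMT2 and EHMT1 fell to -0.19 ± 0.04 and -0.30 ± 0.04, while SUZ12 stood at -0.07 ± 0.03 (adjusted p = 0.102). Of the 2 other EHMT1 probes 1 did not pass the test, and EHMT2 did not pass with the processed signals, at -0.09 (adjusted p = 0.169). In all 3914 genes rose and 3187 fell by limma, 97 and 11 of them at least 2-fold. The balance depended on the scaling, with 2105 risen and 6426 fallen by median centring and 4523 and 2081 by the scanner's processed signals. Adjusted over the list alone, the counts were 30 for NF-kB, 25 for cholesterol, 30 risen and 1 fallen for hypoxia, 39 for lysosome, 40 for G2/M, 43 for G1/S, 25 for histones and 46 for ribosomal proteins. With slide as a block 5541 genes passed, 4870 shared with the 7101, and ATF4 targets, serine synthesis, interferon response and epithelial genes passed as well (0.0492, 0.0345, 0.00661 and 0.0206).

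**Figure D1:**
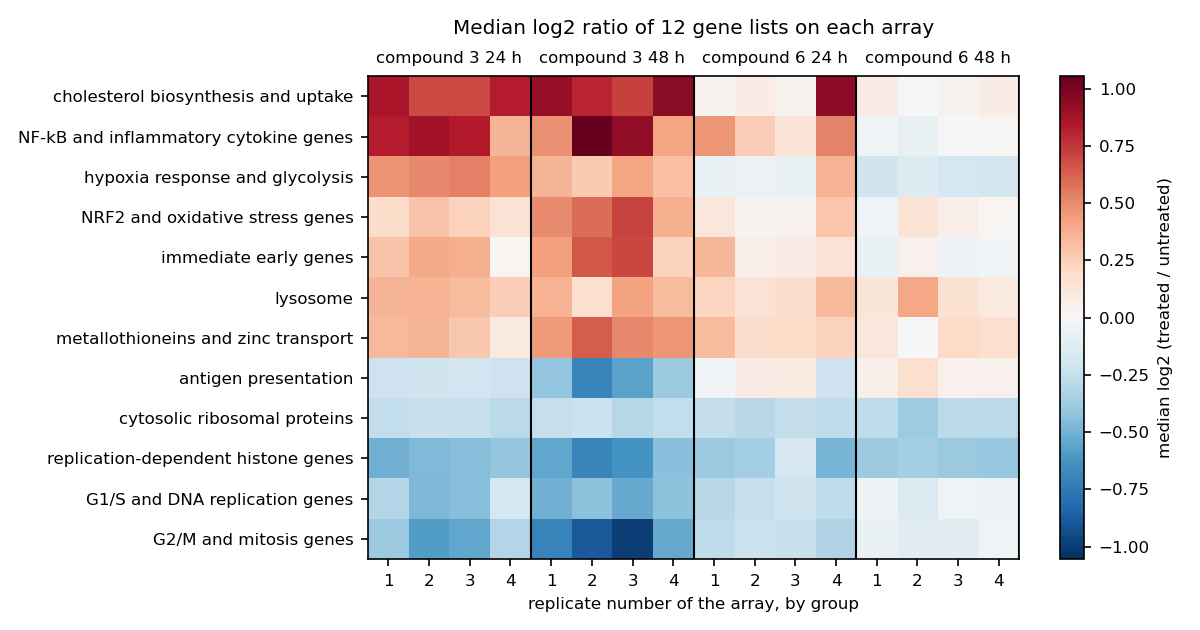
Median log2 ratio of treated over untreated as colour, for 12 gene lists (vertical axis) on each of the 16 arrays, by group and replicate number (horizontal axis). Cholesterol genes lay at 0.78 and 0.86 with compound 3 and G2/M genes at -0.46 and -0.77, and replicate 4 of compound 6 at 24 h stood apart for cholesterol genes at 0.94.

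Compound 3 at 48 h was set against untreated cells to ask the same at the later time. The chemokine gene CCL3 rose most, by 2.89 ± 0.31 (adjusted p = 1.24e-06; chromosome 17, 34415605 to 34415664). It was followed by IL24 at 2.75 ± 0.22, MMP3, a matrix metalloproteinase, at 2.68 ± 0.25 and the inducible HSP70 genes HSPA6 at 2.55 ± 0.18 and HSPA1A at 2.52 ± 0.19. SPINK1, a trypsin inhibitor, rose by 2.54 ± 0.16, with its untreated signal well above background on 3 of 4 arrays, and HKDC1 by 2.53 ± 0.22. Of 32 NF-kB and cytokine genes 25 rose, CXCL2 by 2.53 ± 0.24, and TNFAIP2 fell to -0.68 ± 0.08 (median 0.70; camera 7.24e-08, 0.309 estimated). Of 26 cholesterol genes 25 rose, INSIG1 by 2.11 ± 0.29 (median 0.86; 1.37e-11, 0.290 estimated), and ABCA1 fell to -1.90 ± 0.24. The other large falls were PI16 at -1.70 ± 0.22, SPINK4 at -1.69 ± 0.17, SDPR, which encodes a caveolar protein, at -1.34 ± 0.15 and CDCA7 at -1.29 ± 0.11. All 40 G2/M genes fell, KIF20A to -1.54 ± 0.12 (median -0.77; 2.39e-25, 0.258 estimated), as did all 43 G1/S genes, E2F8 to -1.29 ± 0.07 (median -0.48; 2.37e-19, 0.258 estimated). Of 30 histone genes 27 fell, HIST1H2AB to -1.44 ± 0.12 and HIST1H4C to -1.30 ± 0.11 (median -0.59; 1.73e-14, 0.241 estimated).

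Antigen presentation genes fell in 19 of 22 cases after 48 h of compound 3, with CIITA at -1.06 ± 0.06 and HLA-DMB at -0.99 ± 0.10 (median -0.54; camera 6.34e-08, 0.258 estimated). NRF2 genes rose in 22 of 26 cases, with the aldo-keto reductase AKR1B10 at 2.02 ± 0.12 and HMOX1 at 1.62 ± 0.19 (median 0.58; 2.31e-07, 0.309 estimated). Of 31 immediate early genes 25 rose, EGR1 by 1.61 ± 0.27, while ETV5 and KLF10 fell to -0.22 ± 0.05 and -0.25 ± 0.10 (median 0.54; 1.30e-06, 0.391 estimated). Of 27 ATF4 targets of the integrated stress response 17 rose, CEBPB by 1.38 ± 0.11 and TRIB3 by 1.12 ± 0.09, and PCK2 and CARS fell to -0.14 ± 0.05 and -0.17 ± 0.05 (median 0.36; 0.000116, 0.391 estimated). Of 19 cytosolic heat shock genes 10 rose, HSPA1B by 2.48 ± 0.18, and HSPB1, HSP90AA1, DNAJA1 and HSPA4L fell to -0.41 ± 0.04, -0.24 ± 0.05, -0.15 ± 0.05 and -0.10 ± 0.04. The heat shock median of 0.13 was 0.06 relative to all genes with median centring, which put these at -0.11 (0.0322, 0.552 estimated). Lysosomal genes rose in 34 of 46 cases, ASAH1 by 1.42 ± 0.10 (median 0.33; 1.75e-09, 0.309 estimated). Autophagy genes rose in 23 of 39 cases, SQSTM1 by 1.51 ± 0.11, and ULK2 and ATG16L1 fell to -0.41 ± 0.07 and -0.15 ± 0.04 (4.51e-05, 0.269 estimated). Hypoxia genes rose in 25 of 37 cases, NDRG1 by 1.42 ± 0.13, and CA12 and PKM2 fell to -0.14 ± 0.05 and -0.24 ± 0.04 (median 0.34; 1.84e-05, 0.417 estimated). Metallothionein genes rose in 11 of 13 cases, MT1E by 0.65 ± 0.05, and MT3 fell to -0.18 ± 0.04 (median 0.51; 1.66e-05, 0.279 estimated).

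After 48 h of compound 3 another 4 lists passed. Unfolded protein response genes rose in 12 of 25 cases, HERPUD1 by 0.95 ± 0.06, with PDIA4 and CALR fallen to -0.18 ± 0.05 and -0.23 ± 0.06. The list's median of 0.15 was 0.02 relative to all genes with median centring (0.0322, 0.391 estimated). Apoptosis regulators rose in 9 of 22 cases, BBC3 by 0.85 ± 0.09, with BCL2L1 and BOK fallen to -0.15 ± 0.05 and -0.18 ± 0.04. The apoptosis median of 0.10 was 0.04 relative to all genes with that scaling (0.0322, 0.309 estimated). Ribosomal protein genes fell in 44 of 50 cases (median -0.27; 2.93e-16, 0.241 estimated). All 16 arrays lay at -0.37 to -0.22, so a dye effect stays open. Of the H3K9 methyltransferases and partners 10 of 15 fell, UHRF1 to -1.13 ± 0.06, and SETDB2 rose by 0.77 ± 0.07 along with ZNF644, DNMT3B and DNMT3A at 0.41 ± 0.06, 0.26 ± 0.09 and 0.22 ± 0.05 (0.0274, 0.269 estimated). EZH2 stood at -0.73 ± 0.07 (adjusted p = 2.60e-07), EED at -0.37 ± 0.04, EHMT1 at -0.24 ± 0.04, its 2 other probes not passing, and EHMT2 at -0.22 ± 0.04. SUZ12 stood at -0.10 ± 0.03 (adjusted p = 0.0195, and 0.124 without replicate 3). In all 4529 genes rose and 4146 fell by limma, 181 and 38 at least 2-fold, against 2342 and 7569 with median centring and 5719 and 2615 with the processed signals. Adjusted over the list alone, 26 NF-kB genes rose, 25 cholesterol, 23 NRF2 and 17 ATF4 genes rose, and 29 histone and 19 antigen presentation genes fell. Blocking by slide gave 7413 genes, 6761 shared with the 8675.

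Compound 6 at 24 h was set against untreated cells to ask which transcripts differed after the labelled G9a inhibitor. ASB2 rose most, by 1.40 ± 0.11 (adjusted p = 6.36e-07; chromosome 14, 94400601 to 94400660). HKDC1, GDF15 and LY96 followed at 1.37 ± 0.22, 1.23 ± 0.21 and 1.23 ± 0.16. IL24, SCG5, DOCK9 and ROBO4 rose by 1.21 ± 0.22, 1.21 ± 0.21, 1.14 ± 0.10 and 1.12 ± 0.08. Without replicate 4 the rises were 1.38 for ASB2, 1.15 for HKDC1, 0.84 for GDF15, 1.15 for LY96, 1.04 for IL24, 1.18 for SCG5, 1.01 for DOCK9 and 1.08 for ROBO4, all still past the threshold. HIST1H4J fell most, to -1.09 ± 0.10, followed by RN18S1, an 18S ribosomal RNA probe, at -1.01 ± 0.16, HIST1H2AB at -1.0 ± 0.12 and ZNF865 at -0.95 ± 0.09, whose other probe did not pass. HIST1H4C, E2F8, HIST1H4K and SNAR-A3 stood at -0.94 ± 0.11, -0.92 ± 0.07, -0.89 ± 0.09 and -0.85 ± 0.13. Without replicate 4 the falls were -1.12 for HIST1H4J, -1.16 for RN18S1, -0.97 for HIST1H2AB, -1.04 for ZNF865, -0.84 for HIST1H4C, -0.89 for E2F8, -0.87 for HIST1H4K and -0.96 for SNAR-A3. RN18S1 stood at -0.67 without replicate 1. All genes named here kept their sign on each compound 3 24 h array.

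Among the fixed lists, G1/S genes fell in 35 of 43 cases after 24 h of compound 6 and in 30 without replicate 4, with RRM2 at -0.74 ± 0.07 (median -0.25; camera 2.30e-15, 0.305 estimated). G2/M genes fell in 29 of 40 cases, 22 without replicate 4, with PLK1, a mitotic kinase, at -0.50 ± 0.06 (median -0.26; 2.96e-12, 0.446 estimated). Histone genes fell in 22 of 30 cases, 17 without replicate 4 (median -0.36; 3.16e-11, 0.305 estimated). Ribosomal protein genes fell in 43 of 50 cases, 40 without replicate 4, with RPL23 at -0.64 ± 0.07, although their median of -0.26 turned to 0.03 with the scanner's processed signals (7.21e-24, 0.0837 estimated). That scaling put the median of all genes at 0.13, and relative to it the list's median was -0.09. Of 15 H3K9 methyltransferases and partners 6 fell with and without replicate 4, UHRF1 to -0.57 ± 0.06, and SETDB2 rose by 0.31 ± 0.07. The list's median of -0.07 turned to 0.03 with the processed signals, also -0.09 relative to all genes (0.0228, 0.305 estimated). Serine and glycine synthesis genes fell in 7 of 9 cases, 6 without replicate 4, with PSAT1 at -0.51 ± 0.06 and MTHFD2 at -0.46 ± 0.04, and PSPH rose by 0.18 ± 0.04 (median -0.24; 0.00326, 0.305 estimated).

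Lysosomal genes rose in 29 of 46 cases after 24 h of compound 6 and in 21 without replicate 4, with ASAH1 at 0.61 ± 0.10 and cathepsin B, CTSB, at 0.49 ± 0.07 (median 0.22; camera 7.40e-09, 0.446 estimated). Autophagy genes rose in 19 of 39 cases, 14 without replicate 4, with SQSTM1 at 0.80 ± 0.11, and ATG16L2 and ATG5 fell to -0.33 ± 0.09 and -0.10 ± 0.03 (0.000265, 0.380 estimated). NF-kB and cytokine genes rose in 17 of 32 cases, 10 without replicate 4, with CXCL1 at 0.82 ± 0.20, and IL11 fell to -0.55 ± 0.16 (median 0.35; 7.06e-06, 0.548 estimated). Metallothionein genes rose in 11 of 13 cases, 8 without replicate 4, with MT1F at 0.75 ± 0.11, and MT3 fell to -0.22 ± 0.04 (median 0.23; 0.000116, 0.415 estimated). Immediate early genes rose in 10 of 31 cases, 5 without replicate 4, with DUSP6 at 0.68 ± 0.08 (median 0.17; 0.00742, 0.734 estimated). Cholesterol genes rose in 8 of 26 cases, with LSS, lanosterol synthase, at 0.56 ± 0.08 (median 0.27; 0.000354, 0.688 estimated). Without replicate 4 only 5 of them rose, the median was 0.07 and the list did not pass (0.281). The lists of hypoxia genes, ATF4 targets and heat shock genes passed without replicate 4 but not with all arrays, with medians of -0.09, -0.13 and -0.12 and 11 of 37, 12 of 27 and 7 of 19 genes fallen against 3, 4 and 1 risen (0.0154, 0.0494 and 0.0385). With estimated correlation 0 of 39 lists passed there.

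EZH2 stood at -0.62 ± 0.07 after 24 h of compound 6, -0.63 without replicate 4 (adjusted p = 9.16e-06), and EHMT2, which encodes the labelled target, at -0.14 ± 0.04 (adjusted p = 0.0136; chromosome 6, 31848474 to 31848533), -0.13 without replicate 4. EHMT2 did not pass without replicate 2, at -0.12 (adjusted p = 0.0722), or with median centring, and turned to 0.0065 with the processed signals (adjusted p = 0.935). EED and EHMT1 stood at -0.29 ± 0.04 and -0.19 ± 0.04, the 2 other EHMT1 probes not passing, and SUZ12 at -0.05 ± 0.03 (adjusted p = 0.342). In all 3115 genes rose and 2753 fell by limma, 14 and 3 at least 2-fold, and 2658 rose and 2480 fell without replicate 4. The counts were 5929 and 959 with the processed signals and 2332 and 3057 with median centring. Adjusted over the list alone, 30 lysosomal, 19 NF-kB and 16 cholesterol genes rose, and 38 G1/S, 33 G2/M and 24 histone genes fell. The group lay on slide 2 alone, where the only other array was compound 6 48 h replicate 2. A fit with slide as a block left 2171 genes, 1706 shared with the 5868, with a median standard error of 0.10 against 0.06. HKDC1, GDF15, LY96, SCG5, HIST1H4C and SNAR-A3 were no longer called there, at 0.82 ± 0.40, 0.87 ± 0.40, 0.58 ± 0.23, 0.57 ± 0.35, -0.50 ± 0.17 and -0.51 ± 0.22, nor were EED, EHMT1 and EHMT2, at -0.17 ± 0.07, -0.09 ± 0.07 and -0.08 ± 0.07. Lysosome, serine synthesis and immediate early genes did not pass, with medians of 0.08, -0.06 and 0.09 (0.136 each), nor did autophagy at 0.08 (0.155) and H3K9 methyltransferases at -0.08 (0.191). ATF4 targets, interferon response, antigen presentation and extracellular matrix passed there, each lower (0.0329 each).

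Compound 6 at 48 h was set against untreated cells to ask the same. LY96 rose by 1.12 ± 0.16, as did UCA1 by 1.12 ± 0.11 (adjusted p = 5.18e-06; chromosome 19, 15946035 to 15946092). SCG5, SBSN, SIGLEC15, IL2RG, ECSCR and HCLS1 rose by 1.08 ± 0.21, 1.07 ± 0.12, 1.04 ± 0.16, 1.03 ± 0.21, 1.03 ± 0.13 and 1.01 ± 0.08. IL11 fell most, to -1.01 ± 0.16 (adjusted p = 0.000222). ZNF865, whose other probe did not pass, DDIT4 and ARTN followed at -0.94 ± 0.09, -0.83 ± 0.17 and -0.82 ± 0.08. RPS21, RASD1, PQLC2 and HIST1H4J stood at -0.81 ± 0.04, -0.78 ± 0.11, -0.75 ± 0.10 and -0.74 ± 0.10. All but IL2RG, ECSCR, IL11, DDIT4 and RASD1 kept their sign on each compound 3 48 h array. With the processed signals SIGLEC15 and ECSCR rose by 1.57 and 1.71, and ZNF865, RPS21 and PQLC2 stood at -0.55, -0.40 and -0.36.

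Of 37 hypoxia and glycolysis genes 18 fell after 48 h of compound 6, with LDHA, lactate dehydrogenase A, at -0.56 ± 0.06 and PFKFB4 at -0.48 ± 0.11 (median -0.19; camera 3.66e-06, 0.761 estimated). Histone genes fell in 25 of 30 cases, HIST1H4C to -0.74 ± 0.11 (median -0.35; 6.90e-13, 0.313 estimated). Ribosomal protein genes fell in 44 of 50 cases, RPL23 to -0.60 ± 0.07, and RPL22 rose by 0.15 ± 0.04. Their median of -0.29 turned to 0.0055 with the processed signals, which put the median of all genes at 0.11, and was -0.10 relative to it (3.07e-29, and still called with adjusted p = 0.0396 estimated). Lysosomal genes rose in 22 of 46 cases, ASAH1 by 0.48 ± 0.10 and CTSB by 0.47 ± 0.07 (median 0.19; 4.63e-08, 0.761 estimated). Of 6 measured markers of blood cells, another cell type, 4 rose, HBG1 by 0.81 ± 0.12 (median 0.19; 0.0299, 0.496 estimated). Cholesterol and NF-kB genes had medians of 0.01 and -0.03 (0.395 and 0.872). EZH2 stood at -0.42 ± 0.07 (adjusted p = 0.000330), EHMT2 at -0.26 ± 0.04, EHMT1 at -0.19 ± 0.04, EED at -0.18 ± 0.04 and SUZ12 at 0.06 ± 0.03 (adjusted p = 0.208), of which EHMT2, EHMT1 and EED did not pass with the processed signals. In all 2515 genes rose and 2276 fell by limma, 10 and 1 at least 2-fold, against 5030 and 665 with the processed signals and 1419 and 3347 with median centring. Adjusted over the list alone, 18 hypoxia, 26 histone and 45 ribosomal protein genes fell and 23 lysosomal genes rose. Blocking by slide gave 4965 genes, 4485 shared with the 4791, and G2/M and G1/S genes, at -0.08 and -0.11 without it (0.0594 each), passed at -0.10 and -0.12 (0.0222 and 0.0107).

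Genes called the same way with both compounds were more numerous than independent calls would give. At 24 h 2229 genes rose with both, against 702 expected, and 1869 fell, against 506; at 48 h 1533 rose, against 656, and 1370 fell, against 544. In all 4 groups 1180 genes rose and 970 fell, and 806 and 749 of these had no called difference between the compounds at either time. Across genes, which are not independent replicates, the mean log ratios of the compounds correlated at r = 0.767 at 24 h, 0.641 without compound 6 replicate 4, and at r = 0.481 at 48 h. A simulation in which the compounds changed nothing but shared all untreated RNA gave r = 0.498 with a covariance of 0.00253, below the observed covariances of 0.0356 and 0.0250. A dye preference common to all arrays, or DMSO, could add to these counts and correlations.

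**Figure D2:**
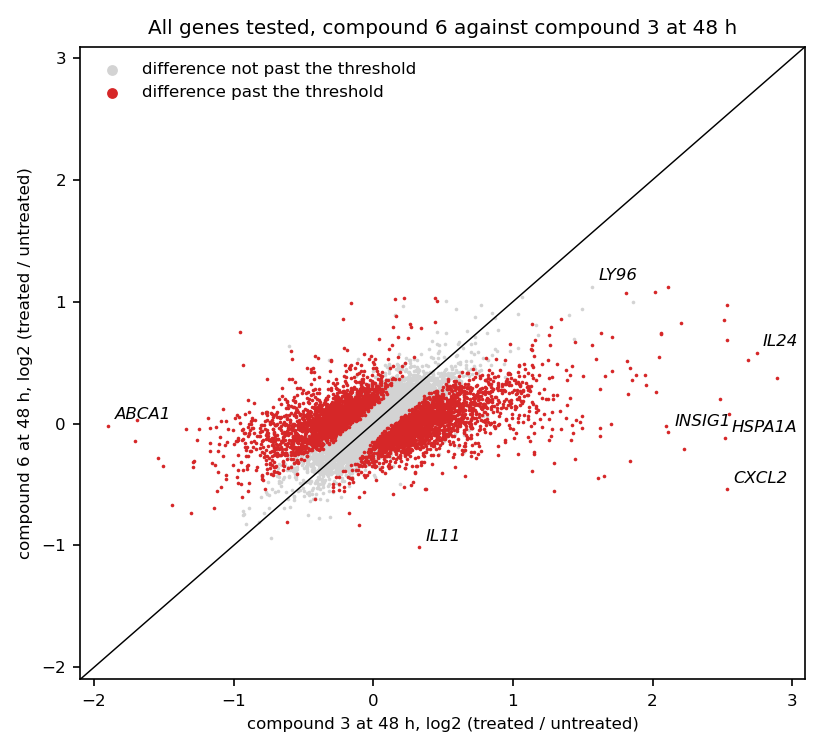
Mean log2 ratio of treated over untreated at 48 h for compound 3 (horizontal axis) and compound 6 (vertical axis); each point is a gene, red where the difference between the compounds passed the threshold and grey where it did not, and the line marks equal values. Across genes r was 0.481, and cholesterol genes lay at a median of 0.86 with compound 3 and 0.01 with compound 6.

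The difference between the compounds at 24 h asked where their responses parted, and it was clearest in hypoxia genes. Of 37 such genes 21 were lower with compound 6, 33 adjusted over the list alone and 29 without compound 6 replicate 4. BNIP3 stood at -1.31 ± 0.20, DDIT4 at -1.28 ± 0.24 and NDRG1 at -1.19 ± 0.19 (median -0.44; camera 1.91e-28, 0.198 estimated). CXCL2, HSPA1A, IL11, HSPA1B and RIMKLA differed by -1.54 ± 0.34, -1.52 ± 0.27, -1.27 ± 0.22, -1.26 ± 0.26 and -1.13 ± 0.16. CYP1A1 was higher with compound 6 by 0.89 ± 0.18 (adjusted p = 0.0286; chromosome 15, 75012562 to 75012621) and VIPR1 by 0.85 ± 0.13. PRDM8, EFNB2, SPSB2, SERPINH1, ATRIP and OR1L6 were higher by 0.52 ± 0.10, 0.48 ± 0.11, 0.43 ± 0.09, 0.41 ± 0.08, 0.39 ± 0.08 and 0.38 ± 0.08, the other probes of PRDM8 and ATRIP not passing. Without replicate 4 the differences were -1.62 for BNIP3, -1.57 for DDIT4, -1.48 for NDRG1, -1.81 for CXCL2, -1.65 for HSPA1A, -1.36 for IL11, -1.41 for HSPA1B, -1.36 for RIMKLA, 1.11 for CYP1A1, 0.91 for VIPR1 and 0.59 for PRDM8. They were 0.60 for EFNB2, 0.52 for SPSB2, 0.48 for SERPINH1, 0.39 for ATRIP and 0.37 for OR1L6.

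Other lists differed at 24 h mostly as whole lists, with few members called. Cholesterol genes were lower with compound 6 in 2 cases, 19 adjusted over the list alone and 20 without replicate 4, STARD4 by -0.79 ± 0.16 (median -0.44; camera 1.73e-10, 0.452 estimated). NF-kB genes were lower in 3 cases, 13 adjusted over the list alone (median -0.35; 1.07e-08, 0.452 estimated). The unfolded protein response was lower in 3 cases, HERPUD1 by -0.58 ± 0.08 and HSPA5 by -0.38 ± 0.06 (median -0.10; 2.90e-05, 0.320 estimated). ATF4 targets, apoptosis regulators and epithelial genes were lower in 1 case each, DDIT4, BBC3 and CLDN4, with medians of -0.19, -0.12 and -0.11 (2.90e-05, 0.00180 and 0.0229; 0.463, 0.320 and 0.463 estimated). Heat shock and autophagy genes were lower in 2 cases each, with medians of -0.10 and -0.05 that turned to 0.06 and 0.03 with median centring, and to 0.0091 for autophagy with the processed signals, but stayed lower than the median of all genes, by -0.02, -0.06 and -0.05 (0.00357 and 0.0203; 0.556 and 0.471 estimated). Lysosome, NRF2 and oxidative phosphorylation had lower medians of -0.11, -0.14 and -0.05, which median centring turned to 0.03 for lysosome and 0.10 for oxidative phosphorylation and the processed signals to 0.02 for the last, or -0.05, 0.02 and -0.04 relative to all genes (0.00251, 0.00257 and 0.0229; 0.556, 0.556 and 0.463 estimated). Higher with compound 6 were the medians of G2/M at 0.22, antigen presentation at 0.20, histones at 0.15, ribosome biogenesis at 0.10 and G1/S at 0.07, without a called member over all genes (2.01e-14, 2.90e-05, 5.87e-06, 2.50e-05 and 2.90e-05). Their adjusted p were 0.452, 0.452, 0.452, 0.463 and 0.532 estimated, and adjusted over the list alone 17 G2/M and 4 G1/S genes were higher. Epithelial genes did not pass without replicate 4 (0.0817).

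EZH2 differed between the compounds at 24 h by 0.11 ± 0.10, 0.10 without replicate 4 (95% interval -0.10 to 0.31; adjusted p = 0.610), and EHMT2 by 0.05 ± 0.06 (-0.07 to 0.17; adjusted p = 0.702). EHMT1, SUZ12 and EED differed by 0.11 ± 0.05, 0.03 ± 0.05 and 0.02 ± 0.06, with adjusted p of 0.320, 0.805 and 0.915. In all 35 genes were higher and 164 lower with compound 6 by limma, and the count rested on scaling and single arrays. Median centring gave 807 and 154, the processed signals 11 and 12, and the authors' values 871 and 945. Without compound 6 replicate 4 the fit gave 424 and 867. Leaving out compound 6 replicates 1, 2 or 3 gave 13, 12 or 7 genes, and leaving out compound 3 replicates 1, 2, 3 or 4 gave 67, 23, 22 or 106. No slide held arrays of both groups. A fit with slide as a block compares them through the 48 h arrays, and its median standard error was 0.15 against 0.08. It called 10 genes, 0 shared with the 199, with BNIP3 at -1.25 ± 0.41, NDRG1 at -1.40 ± 0.39 and CYP1A1 at 0.42 ± 0.35. Of the 17 lists 11 passed, among them hypoxia at -0.55, G2/M at 0.28 and the unfolded protein response at -0.15. The slide 2 term rests on compound 6 48 h replicate 2 alone, so slide stays open. Apoptosis, heat shock, histones and oxidative phosphorylation had medians of -0.15, -0.14, 0.13 and -0.06 but did not pass (0.0548, 0.0729, 0.129 and 0.195), nor did NF-kB at -0.19 (0.0574) and antigen presentation, which turned to -0.09 (0.775). Interferon response, extracellular matrix, mesenchymal and metallothionein genes and ribosomal proteins passed as well (1.04e-05, 0.000473, 0.0227, 0.0441 and 0.00651).

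At 48 h the compounds differed in cell division, lipid and stress genes, among others. The inflammatory genes CXCL2, CCL3, CSF3 and IL24 were lower with compound 6 by -3.07 ± 0.34, -2.52 ± 0.44, -2.44 ± 0.37 and -2.16 ± 0.31 (adjusted p = 4.05e-05 for CXCL2; chromosome 4, 74962985 to 74963044). Of 32 NF-kB genes 22 were lower (median -0.83; camera 4.97e-10, 0.265 estimated). The HSP70 genes HSPA1A, HSPA6 and HSPA1B were lower by -2.64 ± 0.27, -2.47 ± 0.25 and -2.27 ± 0.26, and 9 of 19 heat shock genes were lower (median -0.23; 0.000103, 0.390 estimated). Of 26 cholesterol genes 23 were lower, INSIG1 by -2.18 ± 0.41 (median -0.80; 4.47e-12, 0.265 estimated), while ABCA1 was higher by 1.88 ± 0.35. Of 40 G2/M genes 39 were higher with compound 6, KIF20A by 1.27 ± 0.17 and TOP2A by 0.96 ± 0.11 (median 0.70; 1.87e-31, 0.237 estimated). Of 43 G1/S genes 36 were higher, E2F2 by 1.01 ± 0.18 (median 0.41; 3.80e-21, 0.237 estimated). SPINK4, LTB, PI16, CFP, SDPR and CLDN2 were higher by 1.72 ± 0.24, 1.71 ± 0.38, 1.56 ± 0.31, 1.42 ± 0.34, 1.30 ± 0.21 and 1.23 ± 0.24.

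Of 22 antigen presentation genes 16 were higher with compound 6 at 48 h, HLA-DMB by 1.04 ± 0.13 (median 0.52; camera 1.76e-10, 0.237 estimated). Histone genes were higher in 16 of 30 cases, HIST1H2AB by 0.77 ± 0.17, and HIST1H1C was lower by -0.30 ± 0.07 (median 0.27; 1.06e-05, 0.327 estimated). Hypoxia genes were lower in 30 of 37 cases, NDRG1 by -1.55 ± 0.19 and VEGFA by -0.99 ± 0.16 (median -0.50; 1.30e-15, 0.265 estimated). NRF2 genes were lower in 19 of 26 cases, AKR1B10 by -1.76 ± 0.17 and HMOX1 by -1.72 ± 0.26 (median -0.47; 3.91e-09, 0.265 estimated). Immediate early genes were lower in 21 of 31 cases, EGR1 by -2.06 ± 0.38, and ETV5 was higher by 0.24 ± 0.07 (median -0.50; 1.37e-08, 0.327 estimated). ATF4 targets were lower in 13 of 27 cases, CEBPB by -1.33 ± 0.15 (median -0.30; 1.11e-06, 0.317 estimated). Metallothionein genes were lower in 8 of 13 cases, MT2A by -0.61 ± 0.08 (median -0.38; 1.20e-05, 0.265 estimated). Autophagy genes were lower in 16 of 39 cases, SQSTM1 by -1.11 ± 0.15, and ULK2, ATG7 and ATG16L1 were higher by 0.38 ± 0.10, 0.22 ± 0.07 and 0.17 ± 0.06 (median -0.14; 0.000312, 0.265 estimated). Lysosomal genes were lower in 14 of 46 cases, ATP6V0D2 by -1.19 ± 0.15, with a median of -0.12 that turned to 0.03 with median centring, though -0.05 relative to all genes (0.00470, 0.627 estimated). Apoptosis regulators were lower in 7 of 22 cases, BBC3 by -0.84 ± 0.12 (median -0.16; 0.00507, 0.265 estimated).

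EZH2 was higher with compound 6 than with compound 3 at 48 h by 0.31 ± 0.10 (95% interval 0.11 to 0.52; adjusted p = 0.0237), EED by 0.19 ± 0.06 (adjusted p = 0.0290) and SUZ12 by 0.17 ± 0.05 (adjusted p = 0.0204). In the 4 pairs of arrays with the same number in the authors' values each difference had 1 sign, from 0.25 to 0.38 for EZH2, 0.11 to 0.31 for EED and 0.12 to 0.19 for SUZ12. With these pairs as a block, chosen after the data were seen, the adjusted p were 0.00756, 0.0138 and 0.0110 and 5227 genes passed. In the unpaired fit, without compound 3 replicates 1 or 3 or compound 6 replicates 1, 3 or 4 the adjusted p was 0.0518, 0.0820, 0.0707, 0.0709 or 0.0543 for EZH2 and 0.0849, 0.0768, 0.0744, 0.0867 or 0.0685 for EED. For SUZ12 it was 0.0667, 0.0582, 0.0551 or 0.0528 without compound 3 replicate 3 or compound 6 replicates 1, 3 or 4. No difference was called for EHMT2, at -0.04 ± 0.06 (-0.16 to 0.08; adjusted p = 0.667), or EHMT1, at 0.05 ± 0.05 (adjusted p = 0.524), whose 2 other probes had the opposite sign. In all 2156 genes were higher and 2387 lower with compound 6 by limma, 27 and 96 at least 2-fold, against 3760 and 1225 with median centring and 2127 and 1631 with the processed signals, and of the genes called at 24 h 22 of 35 higher and 151 of 164 lower were called the same way. With slide as a block 4026 genes passed, 3561 shared with the 4543. Within slides 1 and 3 the medians were -0.79 and -0.83 for cholesterol, 0.78 and 0.73 for G2/M, -0.86 and -0.84 for NF-kB and -0.51 and -0.54 for hypoxia. Adjusted over the list alone, 40 G2/M, 39 G1/S and 19 antigen presentation genes were higher, and 23 cholesterol, 30 hypoxia and 21 NRF2 genes were lower.

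**Figure D3:**
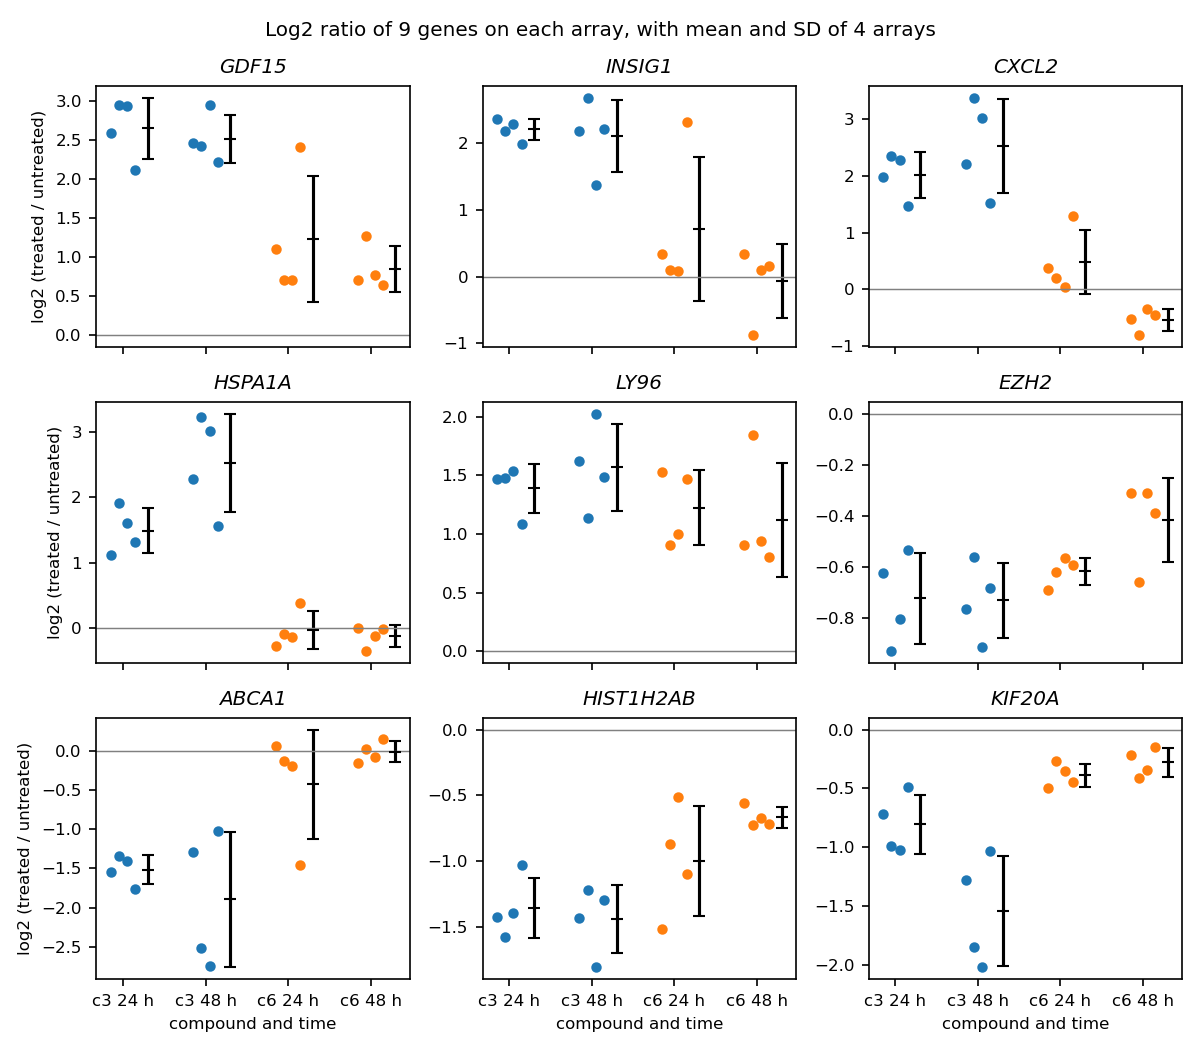
Log2 ratio of treated over untreated (vertical axis) of 9 named genes in the 4 treated groups (horizontal axis); points are single arrays, blue for compound 3 and orange for compound 6, and bars the mean with the SD of 4 arrays. CXCL2 lay at 2.53 with compound 3 at 48 h, and the difference between the compounds at that time was -3.07.

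For compound 3 the difference between 48 h and 24 h asked how the response moved with time. The aldo-keto reductase genes AKR1B10 and AKR1B15 rose further by 1.51 ± 0.17 and 1.21 ± 0.13 (adjusted p = 0.000988 for AKR1B10; chromosome 7, 134225799 to 134225858), the collagenase gene MMP1 by 1.24 ± 0.21 and TRIM54 by 1.24 ± 0.16. SPINK1, FOLR3, ATP6V0D2 and SBSN rose by 1.21 ± 0.22, 1.15 ± 0.19, 0.79 ± 0.15 and 0.75 ± 0.17. The ratio fell for SPINK4 by -1.33 ± 0.24, NNMT by -1.09 ± 0.18, TNFSF10, which encodes the death ligand TRAIL, by -0.94 ± 0.15, GBP4 by -0.88 ± 0.20 and EDN2 by -0.76 ± 0.09. In the treated channel alone these 5 did not fall: EDN2 rose by 0.33 (adjusted p = 0.0451), and the others, at 0.04, 0.47, 0.27 and 0.18, did not pass (0.933, 0.122, 0.284 and 0.600). The ratios of TNFAIP2, CSGALNACT1 and PFKFB4 fell by -0.87 ± 0.12, -0.77 ± 0.11 and -0.75 ± 0.15, the other CSGALNACT1 probe not passing. Ratios of metallothionein genes rose in 8 of 13 cases, MT1L by 0.40 ± 0.08, though MT1L did not rise in the treated channel alone, at -0.00090 (median 0.30; camera 2.01e-06, 0.364 estimated). NRF2 genes did so in 5 of 26 cases, 8 adjusted over the list alone (median 0.24; 7.35e-10, 0.364 estimated). ATF4 targets did so in 5 of 27 cases, 14 adjusted over the list alone, TRIB3 by 0.58 ± 0.12 (median 0.24; 5.96e-08, 0.364 estimated). Ratios of G2/M genes fell in 2 of 40 cases, 30 adjusted over the list alone, KIF20A by -0.74 ± 0.17 (median -0.27; 4.67e-18, 0.364 estimated).

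Further lists whose ratio moved between 24 h and 48 h of compound 3 had few called members. Heat shock genes rose in 3 of 19 cases and immediate early genes in 1 of 31, with NR4A3 fallen by -0.63 ± 0.15 (medians 0.20 and 0.23; camera 2.30e-07 and 3.05e-05; 0.364 and 0.610 estimated). In the treated channel alone MMP1, TRIB3, KIF20A, CSGALNACT1, PFKFB4, LDHA, PDIA4 and CLDN3 did not pass, nor did TRIM22, at 0.073. The medians of cholesterol and ribosome biogenesis genes rose by 0.11 each without a called member (0.0151 and 1.20e-07, 0.740 and 0.367 estimated). Antigen presentation, with CIITA at -0.39 ± 0.08, interferon response, with TRIM22 at -0.45 ± 0.06, and hypoxia, with LDHA at -0.46 ± 0.09, fell in 1, 2 and 3 cases (medians -0.35, -0.20 and -0.11; 1.01e-08, 6.62e-10 and 6.54e-05; 0.364, 0.364 and 0.610 estimated). G1/S, unfolded protein response and epithelial lists had lower medians with 0, 1 and 2 called members, PDIA4, CLDN3 and EPCAM (medians -0.10, -0.07 and -0.06; 3.05e-05, 0.0336 and 0.0198; 0.610, 0.532 and 0.506 estimated). EZH2 moved by -0.01 ± 0.10 (95% interval -0.21 to 0.20; adjusted p = 0.979) and EHMT2, EHMT1, SUZ12 and EED by -0.03 ± 0.06, 0.06 ± 0.05, -0.03 ± 0.05 and -0.07 ± 0.06, none past the threshold. In all 125 genes rose and 168 fell by limma, 64 and 172 with median centring and 52 and 41 with the processed signals. The 293 became 99, 132, 116 or 70 without 24 h replicate 1, 2, 3 or 4 and 91, 75 or 734 without 48 h replicate 2, 3 or 4. Blocking by slide, 284 genes passed, 232 shared with the 293. The unfolded protein response kept its median of -0.07 but did not pass (0.0682), and histones passed (0.0238).

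For compound 6 the same difference with time had 4 called genes. DIAPH3 rose by 0.44 ± 0.06, while BMF fell by -0.50 ± 0.08, COL7A1 by -0.49 ± 0.07 and ARSE by -0.37 ± 0.06. For DIAPH3 the adjusted p was 0.0297 (chromosome 13, 60686155 to 60686214). All 4 calls ended when any single array of either group was left out, with adjusted p = 0.0531 for each without 24 h replicate 4. By limma 1976 genes had an unadjusted p under 0.05. Of list members only BMF was called. Median ratios were higher at 48 h for G1/S by 0.21, G2/M by 0.19, serine synthesis by 0.08 and blood cell markers by 0.11 (camera 1.05e-21, 4.20e-14, 0.000372 and 0.0215; 0.294, 0.359, 0.294 and 0.347 estimated). They were lower for NF-kB by -0.41, hypoxia by -0.23, immediate early genes by -0.19, H3K27 and H3K9 demethylases by -0.17 and metallothioneins by -0.14 (4.20e-14, 9.10e-12, 1.05e-05, 0.000836 and 0.000372; 0.294, 0.347, 0.572, 0.294 and 0.359 estimated). Cholesterol, autophagy and apoptosis lists had lower medians of -0.23, -0.09 and -0.05 (0.000372, 0.000372 and 0.0279; 0.739, 0.354 and 0.359 estimated). Without 24 h replicate 4 the medians were 0.21 for G1/S, 0.17 for G2/M, -0.35 for NF-kB and -0.12 for hypoxia, and cholesterol, at -0.02, no longer passed (0.752). Nor did apoptosis genes (adjusted p = 0.0860), whereas ATF4 targets then passed with a median of 0.11 (0.000900; 0.589 estimated). No gene was called there. EZH2 moved by 0.20 ± 0.10 (95% interval -0.0024 to 0.40; adjusted p = 0.445) and EHMT2 by -0.12 ± 0.06 (adjusted p = 0.438). A block for slide gave 19 genes, 1 of them among the 4, with a median standard error of 0.13 against 0.08. In that fit autophagy, serine synthesis, apoptosis and immediate early genes did not pass, with medians of -0.0049, -0.03, -0.02 and -0.17 (0.869, 0.401, 0.405 and 0.0967). ATF4 targets, antigen presentation and mesenchymal genes, higher, and ribosomal proteins, lower, passed (0.00436, 0.00581, 0.00581 and 0.00436).

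Whether the change with time differed between the compounds was tested as an interaction. By limma 0 genes passed, 2466 had an unadjusted p under 0.05, and 1 passed without compound 6 24 h replicate 4 and 355 without compound 3 48 h replicate 4. Among the lists 14 passed by camera, 3 by fry and 0 with estimated correlation. G2/M genes had a median of 0.48, with 35 members called when adjusted over the list alone, and G1/S genes 0.33, with 27 (2.01e-29 and 5.23e-21; 0.255 for both estimated). Antigen presentation and interferon genes had medians of 0.36 and 0.11, and serine synthesis 0.13 (1.23e-07, 0.000426 and 0.0187; 0.345, 0.484 and 0.441 estimated). Lower medians were those of metallothioneins at -0.43, immediate early genes at -0.39, NRF2 at -0.33, NF-kB at -0.32 and cholesterol at -0.30 (4.45e-09, 1.46e-09, 1.56e-08, 4.34e-05 and 1.42e-05; 0.255, 0.441, 0.441, 0.588 and 0.588 estimated). ATF4 targets, heat shock, ribosome biogenesis and autophagy genes had -0.14, -0.14, -0.11 and -0.07 (0.00451, 0.00217, 0.00122 and 0.0152; 0.588 for each estimated). Without compound 6 24 h replicate 4 the medians were 0.45 for G2/M, 0.34 for G1/S and -0.12 for cholesterol. Autophagy genes and ATF4 targets then did not pass (0.246 and 0.0972), and the unfolded protein response did (adjusted p = 0.0262). A block for slide gave 37 genes, and heat shock, serine synthesis, ATF4 targets and autophagy did not pass, with medians of -0.15, 0.10, 0.04 and 0.03 (0.0600, 0.522, 0.557 and 0.744). Extracellular matrix, epithelial, mesenchymal and ribosomal protein genes passed as well (0.000262, 0.00963, 0.00159 and 0.0236).

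Untreated cells at 48 h were set against those at 24 h, with 8 channels each, to ask what time in culture did without a compound. DHRS3, a retinal reductase gene, rose by 1.78 ± 0.09 (adjusted p = 2.01e-10; chromosome 1, 12628110 to 12628169), PI16 by 1.77 ± 0.19, NNMT by 1.55 ± 0.07 and CLIC3 by 1.38 ± 0.10. SPINK4, RARRES3, TNFSF10 and CST1 rose by 1.37 ± 0.06, 1.29 ± 0.06, 1.21 ± 0.04 and 1.19 ± 0.09. IL24 fell to -1.62 ± 0.14, EGR1 to -1.41 ± 0.11 and MMP3 to -1.24 ± 0.08. They were followed by the hyaluronan synthase gene HAS2 at -1.02 ± 0.07, the cystine transporter gene SLC7A11 at -0.995 ± 0.036 and IL8, MMP1 and CXCL2 at -0.98 ± 0.11, -0.98 ± 0.05 and -0.87 ± 0.08. Of 41 interferon response genes 37 rose, IFIT1 by 1.06 ± 0.08, and IFIT5 fell to -0.15 ± 0.04 (median 0.45; camera 3.81e-16, 0.0352 estimated). Of 27 epithelial genes 22 rose, ITGB4 by 0.88 ± 0.06, and ESRP2 fell to -0.27 ± 0.08 (median 0.35; 7.15e-10, 0.0352 estimated). Of 40 ribosome biogenesis genes 39 fell, RRP12 to -0.72 ± 0.05 (median -0.36; 2.31e-21, 0.0284 estimated). Hypoxia genes rose in 23 of 37 cases with NDRG1 at 0.61 ± 0.08, and ADM, VEGFA and ANGPTL4 fell to -0.21 ± 0.03, -0.38 ± 0.07 and -0.70 ± 0.26 (median 0.25; 2.34e-06, 0.00132 estimated). LXR targets rose in 9 of 11, with ABCA1 at 0.82 ± 0.04 (median 0.28; 5.06e-05, 0.0254 estimated).

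Antigen presentation genes rose in 17 of 22 cases in untreated cells with time, HLA-DMA by 0.71 ± 0.05 (median 0.26; camera 4.79e-05, 0.0543 estimated). Luminal breast epithelial markers, kept as markers of another line, rose in 7 of 14 cases and fell in 2, AGR2 up by 1.12 ± 0.08 (median 0.14; 0.0211, 0.0944 estimated). Blood cell markers rose in 5 of 6, CD14 by 0.65 ± 0.09 (median 0.17; 0.0294, 0.184 estimated). Lysosomal genes rose in 23 of 46 cases, the cathepsin D gene CTSD by 0.67 ± 0.06 (1.77e-06, 0.283 estimated). G2/M genes rose in 25 of 40 cases with 2 fallen, KIF20A up by 0.38 ± 0.04, and cholesterol genes in 10 of 26 with 1 fallen (6.62e-06 and 0.00997; 0.161 and 0.298 estimated). Autophagy genes rose in 20 of 39 cases and fell in 4, GABARAPL1 up by 0.65 ± 0.08 (0.00468, 0.145 estimated). Unfolded protein response genes rose in 12 of 25 cases and fell in 1, and oxidative phosphorylation genes in 14 of 41 and 5, WFS1 and NDUFA2 up by 0.30 ± 0.05 and 0.20 ± 0.04 (0.00797 and 0.0294; 0.10 and 0.416 estimated). Extracellular matrix genes rose in 15 of 27 cases and fell in 5, and mesenchymal genes in 11 of 22 and 5, TIMP3 and S100A4 up by 0.94 ± 0.06 and 1.10 ± 0.04 (0.00796 and 0.00680; 0.416 and 0.277 estimated). Immediate early genes fell in 18 of 31 cases and ATF4 targets in 16 of 27 with 4 risen (medians -0.16 and -0.22; 6.10e-05 and 5.06e-05; 0.277 and 0.213 estimated). NRF2 genes fell in 12 of 26 cases with 3 risen, and NF-kB genes in 15 of 32 with 5 risen (medians -0.12 and -0.21; 0.00666 and 0.0164; 0.325 and 0.416 estimated). Metallothioneins fell in 8 of 13 with 1 risen, aryl hydrocarbon receptor targets in 5 of 7, CYP1A1 to -0.70 ± 0.08, and ribosomal protein genes in 15 of 50 (medians -0.27, -0.49 and -0.04; 0.00566, 0.00311 and 0.0447; 0.262, 0.145 and 0.461 estimated). Among members that went against their list were CDC20, BUB3, SC5DL, SELS, TFF1 and MYB, SQSTM1, ATG3, ATG4B and ATG4D, NDUFS3, CYC1, TFAM and ATP5G1, MMP1, MMP3, MMP14, PLAUR and ADAMTS1, and ZEB1, ZEB2, AXL and CD44, which fell. Those that rose against theirs were DDIT4, NUPR1, VLDLR and JDP2, AKR1C3, ABCC3 and PRDX1, CCL5, CSF1, TNFAIP2, ICAM1 and SOD2, and MT1F.

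EZH2 fell to -0.27 ± 0.06 in untreated cells between 24 h and 48 h (adjusted p = 0.00192), EED to -0.22 ± 0.05 and EHMT1 to -0.17 ± 0.04. EHMT2 fell to -0.11 ± 0.04 (adjusted p = 0.0392). It did not pass, with adjusted p from 0.0501 to 0.0800, without compound 3 24 h replicates 1 or 4, any array of compound 3 at 48 h, compound 6 24 h replicates 1, 2 or 4 or compound 6 48 h replicates 1, 3 or 4. It did not pass with slide as a block either (adjusted p = 0.192). SUZ12 stood at -0.05 ± 0.03 (adjusted p = 0.110). In all 3869 genes rose and 4132 fell by limma, 37 and 5 at least 2-fold. With slide as a block 6958 genes passed, 6597 shared with the 8001, and ribosomal proteins and blood cell markers, at -0.04 and 0.14, did not (0.0811 and 0.0634). Untreated channels with the same number in the authors' values deviated together at 48 h (r = 0.677, 0.334, 0.314 and 0.180) but at 24 h mainly in 1 of 3 pairs (0.401, 0.0934 and 0.0869). Averaged over these pairs, chosen after the data were seen, 5 and 4 channels gave 2875 risen and 2929 fallen genes, and EHMT2 (adjusted p = 0.129) and ribosomal proteins did not pass. Within slides 1, 2 and 3 the interferon median was 0.52, 0.26 and 0.42.

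The remaining 9 of the 39 lists passed in no comparison by camera at the preset correlation. Some passed in other fits, such as with slide as a block PRC2 subunits for compound 3 at 24 h (median -0.12; 0.0480), fatty acid synthesis in the interaction (-0.18; 0.0181) and drug efflux between the compounds at 24 h (-0.13; 0.0432). With median centring PRC2 subunits did so for compound 3 at 24 h (0.0436) and HOX genes between the compounds at 48 h (0.0350). For compound 3 at 48 h, PRC2 subunits had 3 of 11 genes risen and 7 fallen with JARID2 up by 0.50 ± 0.12 (median -0.19; camera 0.144). Genes reported as EZH2-repressed in cancer cells had 9 of 20 risen and 4 fallen, FBXO32 up by 1.86 ± 0.11 and CIITA down (median 0.15; 0.295). HOX genes had 4 of 10 risen with HOXD1 up by 0.54 ± 0.05 (median 0.05; 0.316). Germline and cancer-testis genes had 4 of 10 risen and 2 fallen, fatty acid synthesis 9 of 17 and 2, and p53 targets 11 of 29 and 4 (medians 0.10, 0.16 and 0.07; 0.416, 0.0606 and 0.295). TGF-beta and YAP targets had 10 of 24 risen and 6 fallen, drug efflux genes 6 of 19 and 3, and fibroblast and endothelial markers, of other cell types, 1 of 6 and 2 (medians 0.02, 0.01 and 0.02; 0.726, 0.655 and 0.853). For compound 6 at 48 h 6 of the 20 EZH2-repressed genes rose and 2 fell, and among HOX genes HOXA10 alone was called, at -0.23 ± 0.04 (medians -0.01 and 0.03; 0.974 for both). These medians and counts rest on the list members measured above background, which for HOX genes were 10 of 39.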

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

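Of these tests, those of a wrong file and of the slide for compound 6 24 h replicate 4, those of a common untreated RNA and of the slide for the untreated channels, and the splits of averaged untreated channels were chosen only after the result was seen. A sample stood far from the other 3 of its group in 22 of 184 groups of values, where chance gives about 1 in 20.

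The array labelled compound 6 24 h replicate 4 held the median of cholesterol genes at 0.94, against 0.04 to 0.08 on the other 3 arrays, that of hypoxia genes at 0.36, against -0.07 to -0.06, and that of fatty acid synthesis at 0.13, against -0.04 to -0.02. A wrong file might explain it, since this file was the only 1 of 16 that matched no column of the authors' values, with r = 0.683 at most. The slide spoke against itself as a cause, as the other arrays on it reached r = 0.610 at most with compound 3. Shared untreated RNA was also unlikely, since the treated channel alone differed by 0.319. A biological cause, a culture that responded to compound 6 as others did to compound 3, was not tested and stays a hypothesis.

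Genes changed in the same direction under both compounds could reflect a common response or a dye effect of single probes. Between 2 probes of a gene r was 0.668 for the mean log ratio and 0.795 for the difference between compounds. The gap of -0.127 (95% interval -0.153 to -0.101) is what a dye effect predicts, so that it may account for part of the pattern. Its share stays open, as r also covers other genes. Base composition of the probes explained 0.374% of the variance of the mean log ratio, too little to be the cause. Untreated RNA shared by the authors' numbers was unlikely at 48 h, where other array pairs kept 92.8% of the covariance. The test could not see sharing across numbers and was not run at 24 h. A common response, to both compounds or to DMSO, remains a hypothesis.

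Some untreated channels stood apart from others of their time. Those of compound 3 48 h replicate 3 and compound 6 48 h replicate 2 deviated together at r = 0.677 across genes, a pair chosen for standing apart. Whether 1 untreated RNA was used on arrays of both compounds stays open. Among the other 3 arrays of each compound at 48 h, matching by the authors' numbers gave a mean r of 0.276, 1 of 6 matchings to reach it (next 0.210), too few to decide, and at 24 h mainly 1 of 3 pairs deviated together. The 2 arrays lay on 2 slides, and their treated channels correlated at only 0.0903, which speaks against the slide and against an array artefact as causes. No biological explanation was tested.

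Values of the remaining samples that stood apart are given without a cause, which was not tested. In compound 3 at 24 h these were fatty acid synthesis at 0.13 (replicate 1), LXR targets at -0.070 and luminal markers at 0.083 (replicate 2). Replicate 4, the only array of that group on slide 3, stood apart in heat shock at -0.10, apoptosis at 0.11, NF-kB at 0.36, ribosome biogenesis at -0.24 and its mean r with its group at 0.740. In compound 3 at 48 h they were epithelial genes at -0.18 (replicate 2) and fibroblast and endothelial markers at 0.050 (replicate 3). In compound 6 at 24 h they were demethylases at -0.0059 (replicate 3) and interferon genes at 0.047 (replicate 1). In compound 6 at 48 h replicate 2 stood apart in ATF4 targets at 0.11, antigen presentation at 0.17, extracellular matrix at 0.24, ribosomal proteins at -0.37, SUZ12 at -0.024, its mean r with its group at 0.484 and the SD of its log ratios at 0.270.

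Differences between groups that passed a test were 199 genes and 17 lists between the compounds at 24 h, 4543 genes and 15 lists at 48 h, 293 genes and 14 lists between the times of compound 3, 4 genes and 12 lists between those of compound 6, and 14 lists in the interaction. For the first 4 only the real split of 35 gave as many genes. It gave 199 against at most 147 in the others, 4543 against 293, 293 against 12, and 4 against 1. So few splits cannot exclude chance, nor slide at 24 h. Since untreated channels may share RNA, their splits were run on channels averaged over equal numbers in the authors' values. The real split was the only 1 of 100 with as many genes, 5804 against at most 2415, which makes chance unlikely there. The interaction, with 0 genes, could not be tested in this way. For treated against untreated only 8 splits exist, too few to exclude chance: the real split gave 7101, 8675, 5868 and 4791 genes for compound 3 at 24 h and 48 h and compound 6 at 24 h and 48 h, and the highest other 0, 0, 51 and 0, 1 of 8 in each case. The authors' column labelled compound 6 24 h replicate 1 matched no scanner file and came closest to compound 6 24 h replicate 3 (r = 0.581).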

How the results depend on the processing

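The alternatives named as later in the methods were chosen only after the result was seen: the lists without compound 6 24 h replicate 4, also with estimated correlation, the authors' table with a replicate block, 5 arrays left out together, and the correlations, averaged untreated channels and pairs at 48 h by the table's numbers. Of 6963 alternative values for 345 named results of genes, 6354 kept direction and side of the threshold, 555 lost the call, 8 gained it, 14 reversed and 32 changed sign uncalled. Of 3042 for the 390 results of lists, 2415 kept both, 359 lost the call, 114 gained it, 21 reversed and 133 changed sign uncalled. Dim probes limit the results, since at most 53.2% of probes were well above background on an array. Where no construction is named, the cause was not tested.

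Counts of genes that moved by over 1.5 times were mostly those of the small differences. For compound 6 minus compound 3 at 24 h (199) they were 23 with the processed signals, 961 with median centring, 96 without a filter, 11 with only the groups compared, which leaves fewer arrays, 824 in the treated channel alone, 1816 by the authors' values, and from 7 to 1291 with single arrays left out. For compound 3 at 48 h minus 24 h (293) they were 93 with the processed signals, 118 without a filter, 73 with only the groups compared, 2711 in the treated channel alone and from 70 to 734 with single arrays left out. For compound 6 at 48 h minus 24 h (4) they were 18 without background subtraction, 0 with the processed signals, 1 with median centring, 0 without a filter, 7 with the strict filter, 13 by the authors' values, 5361 in the treated channel alone, which holds the change of the cells with time as well, and 0 without any of the 8 arrays. For the interaction (0) they were 22 without background subtraction, 1 with median centring, and from 0 to 355 with single arrays left out. With 5 arrays left out together compound 6 at 24 h gave 3518, compound 6 minus compound 3 at 24 h 794, compound 3 at 48 h minus 24 h 192 and compound 6 at 48 h minus 24 h 0. Of the 148 list calls camera kept 6 with estimated correlation, 5 in untreated cells. Without compound 6 24 h replicate 4 the other 1 became 12, of 351 tested.

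Slide as a fixed block gave 2171 for compound 6 at 24 h, 10 for compound 6 minus compound 3 at 24 h, 19 for compound 6 at 48 h minus 24 h and 37 for the interaction, and slide as a random block 601 and 17 for compound 6 minus compound 3 at 24 h and for compound 6 at 48 h minus 24 h. With slide as a fixed block the direction turned for interferon and extracellular matrix in compound 6 at 24 h (adjusted p = 0.0329 and 0.0329 by camera), for antigen presentation, extracellular matrix and mesenchymal genes in compound 6 minus compound 3 at 24 h (0.775, 0.000473 and 0.0227), for lysosome, interferon and extracellular matrix in compound 6 at 48 h minus 24 h (0.00298, 0.00941 and 0.00298) and for lysosome in the interaction (0.0410).

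The replicate number as a block gave 58 for compound 6 minus compound 3 at 24 h, 119 for compound 3 at 48 h minus 24 h and 0 for compound 6 at 48 h minus 24 h. The numbers of the scanner files do not pair the arrays: r of the deviations of 24 same-number pairs ran from -0.632 to 0.215, 5 of them above 0.1, against 25 of 72 other pairs, and 0 arrays were matched best by their own number. Pairs at 48 h by the table's numbers gave 5227 for compound 6 minus compound 3 at 48 h and the same 15 lists. With the authors' table and a replicate block the counts were 1897 for compound 6 minus compound 3 at 24 h and 17 for compound 6 at 48 h minus 24 h.

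Median centring turned oxidative phosphorylation in compound 3 at 24 h and 48 h (0.000279 and 6.84e-05), compound 6 at 24 h and 48 h (0.00256 and 0.000996) and compound 6 minus compound 3 at 24 h and 48 h (0.0788 and 0.0395), ribosomal proteins in compound 6 minus compound 3 at 48 h (0.00439), and RPL22 in compound 6 at 48 h (-0.019). It put the median of all genes at -0.11 in compound 3 at 48 h. Without compound 6 24 h replicate 4 hypoxia turned in compound 6 at 24 h (0.0154). With the 5 arrays left out hypoxia turned there (0.00249) and in the interaction (0.00478), and cholesterol and histones in compound 6 at 48 h minus 24 h (0.466 and 0.0293).

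The processed signals turned EHMT2 and ATG5 in compound 6 at 24 h (0.0065 and 0.0078) and CALR in compound 3 at 48 h (0.053). The mean over probes turned PRDX1 in compound 3 at 24 h (0.052) and ATG5 in compound 6 at 24 h (0.042), where another probe has the opposite sign. The treated channel alone turned SPINK4, NNMT, TNFSF10, GBP4, EDN2, TRIM22 and MT1L in compound 3 at 48 h minus 24 h (0.042, 0.47, 0.27, 0.18, 0.33, 0.073 and -0.00090; EDN2 alone called there) and EHMT1 in compound 6 at 48 h minus 24 h (-0.20). The correlation of the compounds across genes was 0.767 at 24 h and 0.481 at 48 h. It was 0.543 with even arrays of compound 3 against odd ones of compound 6 at 24 h, and by the authors' values 0.612, with 0.571 and 0.508 for odd against even and the reverse. At 48 h it was 0.322 by those values with odd against even.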

Other observations

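AhR targets, reporters of the aryl hydrocarbon receptor, had medians of 0.20 and 0.16 with compound 3 and compound 6 at 48 h, neither past the threshold (adjusted p = 0.317 and 0.154 by camera, 39 lists). CA12, a carbonic anhydrase gene among the hypoxia genes, rose by 0.34 ± 0.06 in untreated cells with time and fell to -0.14 ± 0.05 after 48 h of compound 3 (limma).

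Whether the replicate numbers of the authors' table pair the arrays better than those of the scanner files was looked at after the data were seen. For 8 pairs with the same number and time in the table, r of the deviations ran from -0.000789 to 0.443, and for 24 other pairs from -0.509 to 0.276. At 24 h the untreated channels of compound 3 replicate 1 and compound 6 replicates 1 and 4 deviated together, with r of 0.439, 0.431 and 0.401 between them and 0.110 for the next pair. In the untreated channels of compound 3 48 h replicate 3 and compound 6 48 h replicate 2, list medians deviated most for extracellular matrix at -0.23, interferon at -0.19 and aryl hydrocarbon receptor targets at -0.19, and for germline genes at 0.17, serine synthesis at 0.15 and cholesterol at 0.13.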
